A study of Mus musculus with 15 samples.

How the data were processed

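RNA from 15 libraries of mouse neural progenitors was analysed from tables made by the submitters. Per the labels' protocols, RNA was isolated on columns and libraries were built with a TruSeq kit. The submitters' processing notes name STAR, DESeq2 and the mm10 genome, with no versions and no roles. The gene annotation, the counting tool, its strand setting and read filters were not given in the sources used here, so reads of overlapping, antisense or near-identical genes may be shared.

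The first deposited table has 23420 rows of 1 gene each and a column per library. Its sheet is named for RPKM, but the deposited values are counts: there were 0 non-integer cells, library totals differed from 12282038 to 19426544, and the largest library mean of a gene was 100896. The design fixed before the data were examined assumed RPKM values and limma on log2 values. It named edgeR's quasi-likelihood test with the same libraries and contrasts in case of counts, so that test was used, and limma on log2(CPM + 1) became an alternative. In 27 rows a spreadsheet had replaced the gene symbol by a date. These rows held 0.228% to 0.253% of the counts of each library, stayed in the library totals and were not tested. The second deposited table gives 224 genes as a ratio for the 10 transgenic libraries. All 2240 of its cells equalled, within 1e-8, the count divided by the mean count of the 5 controls, so the deposited ratio has no correction for library totals.

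Counts were scaled by TMM in edgeR 4.0.16 (R 4.3.3). Genes with at least 1 CPM in at least 2 libraries were tested, 13982 in all. Each line was compared with the Cre control in 1 model of the 6 groups with all 15 libraries, so that groups of 2 shared an estimate of the spread. Comparisons of a 2-factor with a single-factor line, and the test for departure from the sum of single-factor effects, had a term for the series of the label numbers (21 or 23), since only the controls have libraries of both. Single-factor lines were compared with each other without it. P-values were adjusted by the Benjamini-Hochberg method and the threshold was 0.05. "Rose", "fell", "lower" and "higher" refer to genes past it. A count of genes changed 2-fold also needs an absolute log2 fold change of 1. CPM values are scaled by TMM, and gene levels are means ± SD over libraries.

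Before the data were examined, 27 gene lists were fixed. They were tested with camera (limma 3.58.1) at the preset correlation of 0.01 and at a correlation estimated from the data, and lists needed 3 tested members. The genes of the transgenes compared were left out of the list tests. At the preset correlation 4, 18, 13, 12 and 12 lists passed in the Nkx2.2, Nkx6.1, Olig2, Nkx6.1-P2A-Nkx2.2 and Nkx6.1-P2A-Olig2 lines, and with an estimated correlation 1, 1, 0, 1 and 1, each time the intermediate and dorsal-boundary progenitor factors. The genes named per line were fixed by rule: the 3 factors, the 8 most negative and 8 most positive log2 fold changes among genes past the threshold whose line libraries both lay on the same side of all 5 controls, and up to 4 members past the threshold of each list. For other comparisons these were 5 and 5, and up to 3 per list. Genes outside the rule are said to have been chosen after their values were seen, as are the genes named for the chromosome 18, Hprt and imprinting sections.

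Gene positions came from GENCODE M21, which uses the same assembly as mm10. Of the table's symbols, 21751 matched directly and 1277 through synonyms, and 390 had no single match. Fold bounds for genes with 0 counts in a group use a floor of 3 counts over the group. Ratios for groups with 1 to 3 counts carry an exact 95% interval for counting error only.

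Alternatives were DESeq2 1.42.0, limma on log2(CPM + 1), with pseudocounts of 0.5 and 0.1 and with quantile normalization, and edgeR without an abundance trend, with robust fitting, median-of-ratios scaling, no filter, a filter at 5 CPM, the label series as a term or not, the replicate number or the label number as a block, only the compared groups in the fit, and each library left out. Fits without chromosomes 18 and Y, with the label number as a fixed block and with libraries thinned to the smallest total were added after seeing the data.

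The test was tried on simulated counts drawn from the means and library sizes of the 13982 genes. For the Nkx2.2 line against the control it recovered 37.3%, 74.6% and 92.4% of genes changed by 1.5-fold, 2-fold and 4-fold, with 4.90% false calls. For the Nkx6.1-P2A-Olig2 line against the control these were 46.3%, 74.6% and 90.9%, with 6.00% false calls. Comparisons of a 2-factor with a single-factor line recovered less, 8.27% to 12.1% at 1.5-fold and 45.5% to 50.4% at 2-fold. The highest share of false calls was 7.45%, for Nkx6.1 against Olig2. Of 10 lists planted in the simulation of the Nkx2.2 line, camera found 10, and it called 0 of 20 lists without a change. Genes were drawn independently there, so this could not show false list calls that come from correlation between genes. Libraries of the same group differed by more than sampling noise (chi-square per gene 3.53 to 47.8), so none is a copy of another.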

Results

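Messenger RNA was sequenced from 15 libraries of mouse neural progenitors made from embryonic stem cells of the 129/Ola strain. The cells were kept for 2 days in suspension, treated with 500 nM retinoic acid, and exposed for 12 hours to 1 ug/ml doxycycline, which switched on a transgene. There were 5 transgenic lines with 2 libraries each. Single-factor lines made Nkx2.2, Nkx6.1 or Olig2, transcription factors of the ventral neural tube. The other lines made Nkx6.1 joined by a P2A peptide, which lets 1 transcript give separate proteins, to Nkx2.2 or to Olig2. The reference was the parental line, which carries the Cre recombinase in place of a factor, with 5 libraries. Library totals ranged from 12282038 to 19426544 counts, and each of the 5 control totals was above every total of the transgenic lines. The labels do not say whether replicates were separate cultures, so each p-value measures the spread between these libraries, which may be technical. Among the control libraries, replicate 5 stood apart, with an Olig2 level of 45.1 CPM (counts scaled to library size) against 5.58 to 17.3 in the other 4.

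Each factor was high in its own lines. Nkx2-2 reached 477 ± 40.4 CPM (SD, n = 2) in the Nkx2.2 line and 370 ± 17.2 CPM (SD, n = 2) in the Nkx6.1-P2A-Nkx2.2 line, against 0.671 ± 0.484 CPM (SD, n = 5) in the control. Nkx6-1 reached 645 ± 40.9, 672 ± 7.56 and 669 ± 16.9 CPM (SD, n = 2 each) in the Nkx6.1, Nkx6.1-P2A-Nkx2.2 and Nkx6.1-P2A-Olig2 lines, against 26.2 ± 13.4 CPM (SD, n = 5). Olig2 reached 472 ± 70.3 CPM (SD, n = 2) in its own line and 611 ± 36.7 CPM (SD, n = 2) in the Nkx6.1-P2A-Olig2 line, against 19.6 ± 15.1 CPM (SD, n = 5). Counts per gene do not separate the transgene from the cell's own copy. The annotated genes lie, on mm10, at chromosome 2, 147177546 to 147194243 (Nkx2-2), chromosome 5, 101658139 to 101664996 (Nkx6-1), and chromosome 16, 91225457 to 91228677 (Olig2).

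The study looked for genes that the 3 factors repress, so each line was compared with the control. In the Nkx2.2 line, Pax6 fell from 99.8 ± 18.2 CPM (SD, n = 5) to 12.6 ± 3.43 CPM (SD, n = 2). Pax6 is a homeodomain factor of the intermediate ventral progenitors (chromosome 2, 105668900 to 105697364), and its log2 fold change was -2.99 ± 0.23 (SE; edgeR quasi-likelihood adjusted p = 2.79e-05). Neurog2, a proneural factor, fell by 3.64 ± 0.58 on the log2 scale, and Irx3, a homeodomain factor of the same progenitors (chromosome 8, 91798525 to 91802067), fell by 1.68 ± 0.22. Insm1 (2.80 ± 0.45) and Sim1, a marker of V3 interneurons (2.02 ± 0.38), rose.

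Of the 11 tested intermediate and dorsal-boundary progenitor factors, 3 fell in the Nkx2.2 line (Pax6, Irx3 and Dbx2, -1.40 ± 0.26) and 8 did not pass, while adjusted over the list alone 8 fell. The list's median was -1.40 and it moved down against the other genes (camera adjusted p = 1.21e-17; adjusted p = 0.0256 with an estimated correlation). Among 12 Shh pathway genes, Gli2, an effector of the pathway (-2.33 ± 0.30), and Gas1, a co-receptor (-1.66 ± 0.23), fell, and adjusted over the list alone 8 fell (camera adjusted p = 2.93e-13; adjusted p = 0.0649 with an estimated correlation). The 9 proneural factors held Neurog2 on the lower side and Insm1 on the higher side, and as a list did not pass (camera adjusted p = 0.942). Other members of the fixed lists that passed were Tlx1, of the dorsal interneuron genes (2.18 ± 0.27), Bmp7, a secreted dorsal signal (0.97 ± 0.10), Ctgf (-0.67 ± 0.11) and the cyclin Ccnd2 (-1.16 ± 0.22). Outside the lists, Rlf, a zinc-finger gene on chromosome 4, fell by 2.54 ± 0.14 and held 10.3 ± 1.70 CPM (SD, n = 2), while the other groups had means of 59.4 to 75.8 CPM. Further genes that fell were Fam69c (-3.26 ± 0.57), Foxb1 (-2.75 ± 0.56), the neurotrophin receptor Ntrk2 (-2.44 ± 0.39) and the secreted protease Pappa (-2.39 ± 0.42). Among those that rose were Barx2 (2.05 ± 0.37), Pnmal1 (2.05 ± 0.38) and Tle2, a Groucho-family co-repressor (1.91 ± 0.26). Nkx6-1 (0.83 ± 0.41) and Olig2 (-2.45 ± 0.68) did not pass in this line.

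In total 63 genes were lower and 38 higher in the Nkx2.2 line among 13982 tested (27 and 23 by 2-fold or more), so 62.4% of the changed genes were lower (exact binomial p = 0.0165, two-sided, across genes, which are not independent). Of the genes changed by 2-fold or more 54% were lower (exact binomial p = 0.672). The count of 101 fell to 57 without Nkx2.2 replicate 1, of which 26.3% were lower, to 16 without Nkx2.2 replicate 2, to 55 without control replicate 2 and to 60 without control replicate 4. With each line compared with the controls that share its label series the count was 56, and DESeq2 gave 220.

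In the Nkx6.1 line, the progenitor factors Dbx1 (-4.60 ± 0.81, SE), Prdm12 (-3.03 ± 0.60), Bhlhe22 (-2.48 ± 0.34) and Dbx2 (-2.24 ± 0.28) fell. Dbx1 marks progenitors of V0 interneurons and went from 26.0 ± 14.9 CPM (SD, n = 5) to 1.05 ± 0.343 CPM (SD, n = 2; edgeR quasi-likelihood adjusted p = 0.0211). Neurog2 fell by 2.65 ± 0.52 and Has2, which makes hyaluronan, fell by 2.15 ± 0.28. The genes that rose included the receptor phosphatase Ptprb (1.94 ± 0.36), the Groucho-related Tle6 (1.80 ± 0.22) and Tle2 (1.57 ± 0.26), and Nfix (1.48 ± 0.23).

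Of the 11 intermediate and dorsal-boundary factors, 9 fell in the Nkx6.1 line, Pax6 (-1.40 ± 0.20) and Irx3 (-1.67 ± 0.22) among them, and all 11 adjusted over the list alone (median -1.67; camera adjusted p = 2.07e-31; adjusted p = 0.00266 with an estimated correlation). Of 9 proneural factors 2 fell, Neurog2 among them, and 5 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.000149; adjusted p = 0.22 with an estimated correlation). Of 14 pan-neural progenitor genes 2 fell, Sox2 (-0.63 ± 0.13) and the cadherin Cdh2 (-1.11 ± 0.23), and 6 adjusted over the list alone (camera adjusted p = 1.36e-06; adjusted p = 0.248 with an estimated correlation). Single members of other lists that fell were Hhip, an inhibitor and target of Shh signalling (-1.16 ± 0.22), the retinoic acid binding protein Crabp1 (-1.13 ± 0.18), Lmo4 (-0.83 ± 0.10), Elavl2 (-0.75 ± 0.14), Hoxa4 (-0.48 ± 0.10), Sox17 (-0.64 ± 0.10), Ctgf (-0.58 ± 0.11) and Plk2 (-0.52 ± 0.09). The 23 tested Hox genes held 1 member that fell, and 8 adjusted over the list alone (camera adjusted p = 5.59e-09; adjusted p = 0.119 with an estimated correlation). At the preset correlation whole chromosomes 3, 13 and X also moved down and 11 up in this line (camera adjusted p = 0.0177, 0.0136, 0.00026 and 0.0177). Median log2 values against the control mean on chromosomes 3, 13 and X were -0.104, -0.111 and -0.164 in Nkx6.1 replicate 1. In replicate 2 they were -0.0347, -0.0231 and -0.0531. Outside the lists, Ndnf (-2.69 ± 0.43) and Nebl (-2.25 ± 0.36) fell, and Dnaic1 (1.53 ± 0.27), Ccdc88b (1.20 ± 0.24) and Syt17 (1.17 ± 0.21) rose. Olig2 (0.26 ± 0.52) and Nkx2-2 (-3.28 ± 1.11; edgeR quasi-likelihood adjusted p = 0.173) did not pass. Nkx2-2 had 2 counts over both libraries, a ratio of 10.8 to the control (95% exact interval 2.87 to 91.2, counting error only).

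There were 79 lower and 24 higher genes in the Nkx6.1 line (34 and 12 by 2-fold or more), so 76.7% were lower (exact binomial p = 4.98e-08, across genes). The count of 103 rested on the libraries used: without Nkx6.1 replicate 1 it was 1, and without control replicates 1, 2, 3, 4 and 5 it was 283, 40, 64, 47 and 168. DESeq2 called 486 genes, and comparison with the controls of the same label series called 56.

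In the Olig2 line, 62 genes were lower and 198 higher (25 and 30 by 2-fold or more), and most of the higher genes lay on 1 chromosome. Of 370 tested genes of chromosome 18, 158 rose and 1 fell, with a median log2 fold change of 0.52 (camera adjusted p = 1.84e-94; adjusted p = 4.40e-07 with an estimated correlation). All 5 tested genes of the Y chromosome fell: Ddx3y, Uba1y and Usp9y had no counts in either Olig2 library and were at least 456-fold, 21.8-fold and 12.9-fold lower, against a floor of 3 counts over the group. Uty (3 counts) and Eif2s3y (1 count) were 232 times (95% exact interval 79.3 to 1126, counting error only) and 768 times (138 to 30334) below the control. In the Nkx6.1-P2A-Olig2 line, which also makes Olig2, 0 of these 5 genes passed and their median log2 fold change was -0.67. Ddx3y had 430 and 442 counts there, so the near absence of Y reads did not extend to that line. Its cause was not tested. With the genes of chromosomes 18 and Y left out of the fit, 20 genes changed in the Olig2 line, 10 lower and 10 higher, while 56 lower and 40 higher genes of the fit to all genes lay outside these chromosomes.

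These 20 included the transgene and, on the higher side, Rgs16 (2.91 ± 0.25, SE) and Rgs8 (2.72 ± 0.37), regulators of G-protein signalling, the matrix protein Ltbp2 (2.64 ± 0.36) and the neuronal differentiation factor Neurod1 (2.46 ± 0.39), in the fit to all genes. Rgs16 had an edgeR quasi-likelihood adjusted p of 6.00e-05. On the lower side were Plagl1, an imprinted zinc-finger gene (-3.70 ± 0.53), Has2 (-2.12 ± 0.28) and Bhlhe22 (-2.10 ± 0.32). Genes that passed only in the fit to all genes are given next with that fit's values. Between the fits the log2 fold changes of the genes named for this line moved by at most 0.0146, so the calls ended with the adjusted p. They included Neurog2 (2.05 ± 0.37), the Notch ligands Dll4 (2.21 ± 0.50) and Dll3 (1.65 ± 0.36), the Notch target Heyl (1.42 ± 0.29), Mfng, which modifies Notch (1.67 ± 0.37), Btbd17 (2.40 ± 0.52), Dlk2 (2.10 ± 0.49), Pax6 (-1.13 ± 0.20), Irx3 (-1.15 ± 0.21), Hhip (-0.92 ± 0.21), Hoxd1 (-1.27 ± 0.26), Meox1 (-1.15 ± 0.25), Plk2 (-0.40 ± 0.09) and Aen (-0.39 ± 0.08). Mbp (0.81 ± 0.11), a myelin gene, lies on chromosome 18.

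Of 17 Notch pathway genes 4 rose in the Olig2 line, and 10 adjusted over the list alone (median 0.85; camera adjusted p = 9.27e-08; adjusted p = 0.305 with an estimated correlation). Of 9 proneural factors 2 rose, Neurog2 and Neurod1, and 6 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000552; adjusted p = 0.322 with an estimated correlation). Of the 11 intermediate and dorsal-boundary factors 3 fell, and 6 adjusted over the list alone (median -0.93; camera adjusted p = 3.87e-07; adjusted p = 0.185 with an estimated correlation). Of 15 p53 response genes 2 fell, Aen and Plk2, and 10 adjusted over the list alone (camera adjusted p = 9.27e-08; adjusted p = 0.185 with an estimated correlation). Nkx2-2 (0.09 ± 0.61) and Nkx6-1 (-0.25 ± 0.45) did not pass. Among all 260 changed genes 23.8% were lower (exact binomial p = 9.59e-18, across genes), a share set by chromosome 18, and 45.5% of those changed by 2-fold or more (exact binomial p = 0.590). The count of 260 was 106 without Olig2 replicate 2 and 444 without control replicate 5, and DESeq2 gave 432.

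**Figure D1:**
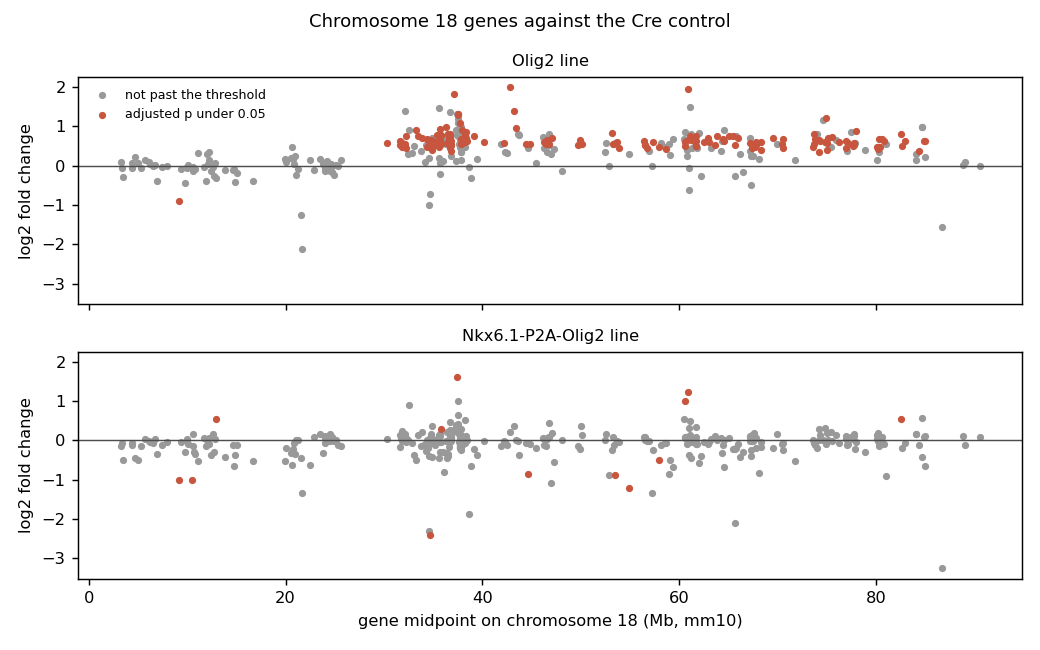
Log2 fold change against the Cre control (vertical axis) of each tested gene of chromosome 18 by its midpoint in Mb on mm10 (horizontal axis), in the Olig2 line (top) and the Nkx6.1-P2A-Olig2 line (bottom); red points passed the adjusted p threshold of 0.05. In the Olig2 line 158 genes rose, all past 25 Mb, and in the Nkx6.1-P2A-Olig2 line 6 rose and 7 fell.

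In the Nkx6.1-P2A-Nkx2.2 line, the strongest falls were of Neurog2 (-6.57 ± 0.85, SE) and Dbx1 (-6.48 ± 1.01). Neurog2 went from 14.1 ± 6.84 CPM (SD, n = 5) to 0.143 ± 0.0242 CPM (SD, n = 2; edgeR quasi-likelihood adjusted p = 0.000848). Olig3, a dorsal progenitor factor (-3.98 ± 0.70), Prdm13 (-4.72 ± 0.98), Has2 (-3.70 ± 0.33), Pax6 (-3.44 ± 0.24) and Irx3 (-2.69 ± 0.24) fell as well. Sost, a secreted Wnt inhibitor (2.63 ± 0.26), Ptprb (2.53 ± 0.35), the cadherin Cdh22 (2.43 ± 0.30), Bhlhe23 (2.79 ± 0.62), Six2 (2.22 ± 0.31) and Il1rl2 (2.21 ± 0.36) rose.

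Of the 11 intermediate and dorsal-boundary factors 9 fell in this line, Sp8 (-1.57 ± 0.22) and Prdm12 (-3.27 ± 0.64) among them, and all 11 adjusted over the list alone (median -2.19; camera adjusted p = 6.46e-37; adjusted p = 0.00189 with an estimated correlation). Of 17 dorsal progenitor factors 6 fell, such as Zic2 (-1.29 ± 0.24), 1 rose (Bmp7, 1.34 ± 0.10), and 11 fell and 1 rose adjusted over the list alone (camera adjusted p = 2.39e-05; adjusted p = 0.257 with an estimated correlation). Of 12 Shh pathway genes 4 fell, among them Hhip (which fell by 2.00 ± 0.23), Gli2 (-2.57 ± 0.31) and Gas1 (-1.88 ± 0.24), and 8 adjusted over the list alone (camera adjusted p = 4.87e-11; adjusted p = 0.0595 with an estimated correlation). Of 7 V2 interneuron genes 2 fell, Gata3 (-1.55 ± 0.25) and Lmo4 (-0.84 ± 0.10), also adjusted over the list alone (camera adjusted p = 2.64e-05; adjusted p = 0.0501 with an estimated correlation). Of 10 neural crest genes 3 fell, Twist1 (-1.69 ± 0.28), Pax3 (-1.95 ± 0.45) and Tfap2b, and 1 rose, the receptor Erbb3 (0.72 ± 0.15), with 4 and 1 adjusted over the list alone (camera adjusted p = 0.00697; adjusted p = 0.326 with an estimated correlation). Hypoxia and glycolysis genes moved up (camera adjusted p = 3.72e-06; adjusted p = 0.28 with an estimated correlation), with Vegfa (0.77 ± 0.18) the 1 of 14 that rose and 7 adjusted over the list alone. Further list members that passed were Sox9 (0.89 ± 0.13), Hes1 (0.49 ± 0.11), Crabp2 (0.58 ± 0.14), Rarb (-0.83 ± 0.17), Crabp1 (-0.80 ± 0.18), Tlx1 (1.36 ± 0.30), Nkx6-2 (-1.82 ± 0.45), Sox17 (-0.64 ± 0.10) and Atf4 (-0.42 ± 0.08). Nkx6-2 and Crabp2 missed the threshold without chromosomes 18 and Y (edgeR quasi-likelihood adjusted p = 0.0531 and 0.0542). Fam69c and Tfap2b, with 3 counts each in this line, were 21.9 times (95% exact interval 7.38 to 107, counting error only) and 19.4 times (6.55 to 95.1) below the control, and Nkx2-1, with 1 count, 19.1 times (3.31 to 768). Olig2 (-1.13 ± 0.60) did not pass.

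The Nkx6.1-P2A-Nkx2.2 line had 246 lower and 153 higher genes (123 and 53 by 2-fold or more), so 61.7% were lower (exact binomial p = 3.74e-06, across genes). The count of 399 was 103 and 89 without replicate 1 or 2 of the line, and 250 without control replicate 2 and 246 without control replicate 4. It was 202 against the controls of the same label series, of which 184 were shared, and 650 with DESeq2.

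In the Nkx6.1-P2A-Olig2 line, Plagl1 (-4.97 ± 0.60, SE), Dbx1 (-4.55 ± 0.81), Has2 (-4.20 ± 0.34), Prdm12 (-3.59 ± 0.66) and Prdm13 (-3.47 ± 0.82) fell. Has2 went from 29.3 ± 6.51 CPM (SD, n = 5) to 1.58 ± 0.155 CPM (SD, n = 2; edgeR quasi-likelihood adjusted p = 7.92e-05). Olig3 (-3.35 ± 0.62), Wnt1, a dorsal midline signal (-2.94 ± 0.50), and Irx3 (-2.32 ± 0.23) were also lower. The receptors Gpr12 (3.18 ± 0.45) and Sstr3 (2.58 ± 0.43), Ptprb (2.48 ± 0.34), Btbd17 (2.34 ± 0.52), Lfng, which modifies Notch (2.23 ± 0.48), and Sost (2.07 ± 0.26) rose. Neurog2 (0.35, edgeR quasi-likelihood adjusted p = 0.713), which was named after its value was seen, and Nkx2-2 (-1.36 ± 0.80) did not pass.

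Of the 11 intermediate and dorsal-boundary factors 9 fell, with Pax6 at -1.43 ± 0.20, Dbx2 at -2.13 ± 0.28 and Bhlhe22 at -2.12 ± 0.32, and all 11 adjusted over the list alone (median -2.12; camera adjusted p = 6.49e-27; adjusted p = 0.00566 with an estimated correlation). Of 17 dorsal progenitor factors 6 fell and 2 rose, with Pax7 at 1.53 ± 0.30, and 10 fell and 2 rose adjusted over the list alone (camera adjusted p = 5.51e-06; adjusted p = 0.224 with an estimated correlation). Of 17 Notch pathway genes 4 rose, Lfng, Mfng (1.84 ± 0.37), Hes1 (0.62 ± 0.11) and Hes6 (0.43 ± 0.10), and 7 adjusted over the list alone (camera adjusted p = 1.60e-05; adjusted p = 0.294 with an estimated correlation). Of 17 pluripotency genes 2 fell, Prdm14 (-2.22 ± 0.46) and Klf5 (-1.20 ± 0.25), and 11 adjusted over the list alone (camera adjusted p = 2.38e-10; adjusted p = 0.224 with an estimated correlation). Other members that passed included Hhip (-1.69 ± 0.23), Nkx6-2 (-2.16 ± 0.46), the sensory neuron factor Pou4f1 (-1.49 ± 0.28), Tfap2a (-1.72 ± 0.40), Sox17 (-0.82 ± 0.10), Gata3 (-0.93 ± 0.23), Fn1 (-0.60 ± 0.13), Lmo4 (-0.43 ± 0.10), Sox9 (0.96 ± 0.13), Crabp2 (0.80 ± 0.14) and Mbp (0.55 ± 0.12). Outside the lists, Xlr3c, a member of an X-linked multicopy family whose reads may be split among copies, fell by 3.77 ± 0.64. Rmst had 2 counts in this line, about 14 times below the control (95% exact interval 3.76 to 118, counting error only).

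The Nkx6.1-P2A-Olig2 line had 255 lower and 142 higher genes (109 and 39 by 2-fold or more), so 64.2% were lower (exact binomial p = 1.53e-08, across genes). The count of 397 was 142 and 81 without replicate 1 or 2 of the line, and 257 without control replicate 2 and 233 without control replicate 4. It was 187 against the controls of the same label series, of which 157 were shared, and 714 with DESeq2.

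**Figure D2:**
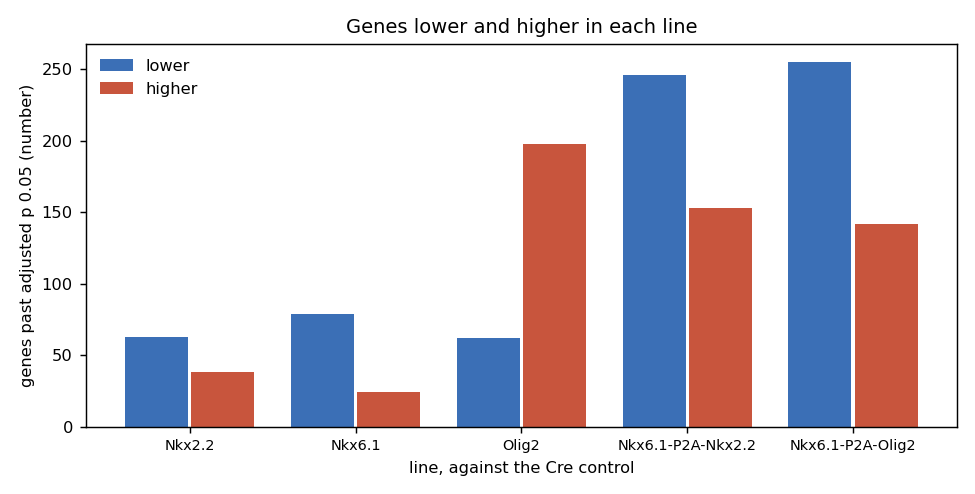
Number of genes past an adjusted p of 0.05 (vertical axis) that were lower (blue) or higher (red) in each transgenic line than in the 5 control libraries. The Nkx6.1-P2A-Nkx2.2 and Nkx6.1-P2A-Olig2 lines had 399 and 397 changed genes, and 158 of the 198 higher genes in the Olig2 line were on chromosome 18.

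Across the lines, 5 genes were lower in all 5: Pax6, Irx3, Has2, Osr1 and the Groucho-family co-repressor Tle1. Osr1 and Tle1 were named after their values were seen. In the Olig2 line, with the genes of chromosomes 18 and Y left out of the fit, Pax6 and Irx3 missed the threshold (edgeR quasi-likelihood adjusted p = 0.0531 and 0.0560), at log2 fold changes of -1.11 and -1.14. Tle1 fell by 0.51, 0.67, 0.52, 1.25 and 0.95 on the log2 scale in the Nkx2.2, Nkx6.1, Olig2, Nkx6.1-P2A-Nkx2.2 and Nkx6.1-P2A-Olig2 lines. A further 13 genes were lower in 4 lines, 40 in 3, 113 in 2 and 282 in 1. The Nkx2.2 and Nkx6.1 lines shared 14 lowered genes, where independent lists of these sizes would share 0.356. Simulated unchanged groups against the same controls shared 0. Such groups hold no changed genes, so this 0 cannot show how much the shared controls add to lists of these sizes. The Nkx2.2 and Olig2 lines shared 8 (0.279 for independent lists), and the Nkx6.1 and Olig2 lines 11 (0.35). The Nkx6.1-P2A-Nkx2.2 line shared 49 with the Nkx2.2 line (1.11), 49 with the Nkx6.1 line (1.39) and 15 with the Olig2 line (1.09). The Nkx6.1-P2A-Olig2 line shared 25 with the Nkx2.2 line (1.15), 46 with the Nkx6.1 line (1.44) and 20 with the Olig2 line (1.13). In the fit without chromosomes 18 and Y, the 10 lowered genes of the Olig2 line shared 4, 5, 6 and 7 with the Nkx2.2, Nkx6.1, Nkx6.1-P2A-Nkx2.2 and Nkx6.1-P2A-Olig2 lines. The 2-factor lines shared 124 with each other (4.49). Each pair was also counted with separate control libraries for its lines, which left 3 to 75 shared genes per pair. All control libraries come from the parental line with Cre at the locus, and no line carries an inert sequence there. Effects of the factors on the shared genes therefore cannot be told apart from a difference of the parental line or of the exchange.

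**Figure D3:**
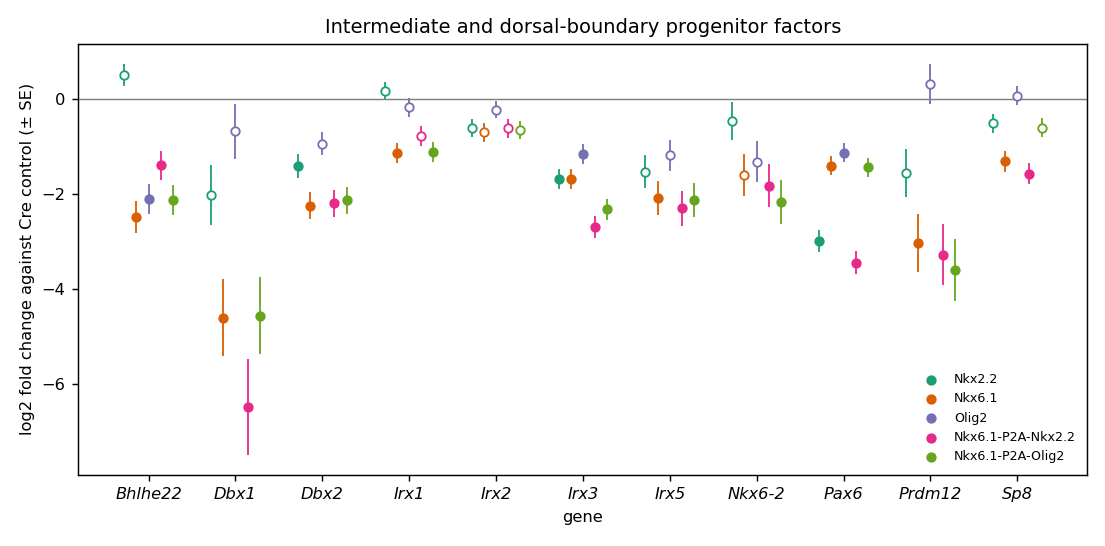
Log2 fold change against the Cre control (vertical axis, ± SE) of the 11 tested intermediate and dorsal-boundary progenitor factors (horizontal axis) in the 5 lines; filled points passed the adjusted p threshold of 0.05. Pax6 and Irx3 passed in all 5 lines, and Dbx1 passed at -4.60, -6.48 and -4.55 in the Nkx6.1, Nkx6.1-P2A-Nkx2.2 and Nkx6.1-P2A-Olig2 lines.

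The single-factor lines were compared with each other. Between the Nkx2.2 and Nkx6.1 lines, 34 genes were lower and 47 higher in the Nkx2.2 line. Pax6 was lower in the Nkx2.2 line (-1.59 ± 0.24, SE; edgeR quasi-likelihood adjusted p = 0.0118), as were Gli2 (-2.06 ± 0.33), Rlf (-2.89 ± 0.15), the cytochrome Cyp1b1 (-1.95 ± 0.25), Bcl3 (-1.91 ± 0.38) and Hoxb1 (-1.88 ± 0.36). Higher in the Nkx2.2 line were Insm1 (3.97 ± 0.67), Kctd12b (3.69 ± 0.63), Bhlhe22, Wnt1 (2.83 ± 0.50), Sim1 (2.73 ± 0.53), the growth cone gene Gap43 (1.92 ± 0.39), Hoxc6 (1.63 ± 0.30), Foxa1 and Irx1 (1.30 ± 0.24). The count of 81 was 42 and 15 without Nkx2.2 replicate 1 or 2, and 4 and 20 without Nkx6.1 replicate 1 or 2.

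Against the Olig2 line, the Nkx2.2 line had 193 lower and 64 higher genes and the Nkx6.1 line 216 and 47. Of these, 65 and 58, and 81 and 42, lay outside chromosomes 18 and Y, and with those chromosomes left out of the fit 33 and 30, and 28 and 15, passed. Neurog2 was lower in the Nkx2.2 line (-5.69 ± 0.63, SE; edgeR quasi-likelihood adjusted p = 0.000458) and in the Nkx6.1 line (-4.69 ± 0.58), and Neurod1 was lower by -3.52 ± 0.56 and -3.69 ± 0.57. In the Nkx2.2 line Rgs16 (-3.84 ± 0.36), Fam69c on chromosome 18 (-4.25 ± 0.60), Foxc2 (-1.93 ± 0.39), Pax6 (-1.86 ± 0.24) and Gli2 (-1.67 ± 0.33) were lower (Foxc2 only in the fit to all genes, with an edgeR quasi-likelihood adjusted p of 0.0517 in the other), and Bhlhe22 (2.61 ± 0.35), Tlx1 (1.95 ± 0.36) and Bmp7 (0.95 ± 0.13) higher. In the Nkx6.1 line Dbx1 (-3.92 ± 0.86), the Notch target Hes5 (-3.60 ± 0.77), Neurog1 (-3.52 ± 0.78), Prdm12 (-3.35 ± 0.66), Pou3f2 (-2.53 ± 0.59), Jag1 (-2.02 ± 0.45), Sp8 (-1.38 ± 0.25) and the neurofilament Nefl (-1.07 ± 0.20) were lower. Meox1 (1.70 ± 0.29) and the retinoic acid oxidase Cyp26b1 (1.09 ± 0.25) were higher there. Of these, Dbx1, Hes5, Neurog1, Prdm12, Pou3f2, Jag1 and Cyp26b1 passed only in the fit to all genes (edgeR quasi-likelihood adjusted p = 0.0869, 0.0869, 0.0890, 0.0583, 0.102, 0.0880 and 0.106 without chromosomes 18 and Y), with log2 fold changes that moved by at most 0.0226. The count of 257 was 125 and 128 without Nkx2.2 replicate 1 or 2 and 163 and 123 without Olig2 replicate 1 or 2, and that of 263 was 91 without Nkx6.1 replicate 1 and 116 without Olig2 replicate 2. With only the compared groups in the fit, nearly all of the 257 were lost, as given with the processing below.

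The 2-factor lines were compared with single-factor lines in a model with a term for the label series, since their libraries carry a different series of label numbers. Few genes passed. Against the Nkx6.1 line, the Nkx6.1-P2A-Nkx2.2 line had 2 lower genes, both imprinted, Mest (-3.12 ± 0.33, SE; edgeR quasi-likelihood adjusted p = 0.00388) and Plagl1 (-2.44 ± 0.35), and 2 higher ones, Nkx2-2 and Sost (2.83 ± 0.39). Plagl1 had an edgeR quasi-likelihood adjusted p of 0.0497, and of 0.0509 without chromosomes 18 and Y. Against the Nkx2.2 line the Nkx6.1-P2A-Nkx2.2 line had 10 lower genes, among them Plagl1 (-2.97 ± 0.35), Mest (-2.80 ± 0.33), Nxf3 (-2.23 ± 0.29), Eya1 (-2.16 ± 0.31) and Hand2 (-1.97 ± 0.32), and 3 higher, Rlf (2.92 ± 0.19), Pcca (0.98 ± 0.16) and Tmtc4 (0.82 ± 0.13). Nkx6-1, which the transgene adds, did not pass at 677 and 666 CPM against 28.4 and 65.1 CPM. Against the Nkx6.1 line, the Nkx6.1-P2A-Olig2 line had 11 lower genes and 0 higher, with 1448 at an unadjusted p under 0.05 in either direction and 16 higher by DESeq2. Olig2, which its transgene carries, did not pass at 586 and 637 CPM against 22.8 and 24.1 CPM, so a low count here does not mean few differences. The 11 lower genes included Plagl1 (-5.31 ± 0.41), Nnat (-3.60 ± 0.46) and Nxf3 (-2.44 ± 0.30), and Xlr3c (-5.34 ± 0.61) of the Xlr family. Against the Olig2 line it had 69 lower and 12 higher genes, of which 36 and 9 lay outside chromosomes 18 and Y, and 21 and 6 passed with those left out of the fit. Neurod1 (-2.99 ± 0.54), Prame (-3.13 ± 0.57), Slc44a3 (-2.56 ± 0.49), Nnat (-2.45 ± 0.46) and Plagl1 (-2.59 ± 0.45) were lower, and Sost (2.87 ± 0.40), Meox1 (2.00 ± 0.33) and Hoxd1 (1.96 ± 0.38) higher. Of these, Neurod1, Prame, Slc44a3, Nnat and Hoxd1 passed only in the fit to all genes (edgeR quasi-likelihood adjusted p = 0.0552, 0.0552, 0.0670, 0.0663 and 0.0803 in the other). Leaving out single libraries gave 1 to 12 in place of 4 genes, 1 to 21 in place of 13, 5 to 23 in place of 11 and 8 to 356 in place of 81, with the highest of each range reached without control replicate 4 and the 8 without Nkx6.1-P2A-Olig2 replicate 1. Without the term for the label series the counts were 30, 30, 82 and 452, of which 3, 9, 6 and 72 were shared with the 4, 13, 11 and 81.

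Whether a 2-factor line departed from the sum of its single-factor effects, on the log2 scale, was also tested. In the Nkx6.1-P2A-Nkx2.2 line 1 gene did, Rlf (2.64 ± 0.24, SE; edgeR quasi-likelihood adjusted p = 0.00157), which was low in the Nkx2.2 line alone. In the Nkx6.1-P2A-Olig2 line 3 did, the Y-linked Ddx3y, Eif2s3y and Uty, which were near 0 counts in the Olig2 line, and without chromosomes 18 and Y 0 did by edgeR, while 1751 genes had an unadjusted p under 0.05 in the test of all genes and DESeq2 called 68. In simulated data for the first of these tests 26.7% of genes departing 2-fold were recovered. Without the term for the label series, 3 and 188 genes departed in the Nkx6.1-P2A-Nkx2.2 and Nkx6.1-P2A-Olig2 lines.

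A second table deposited by the authors gave ratios to the control mean for a selection of genes, each with a mean ratio of 0.5 or less in at least 1 line. It was chosen on these libraries, so its direction is not independent evidence. In the authors' deposited table both libraries had ratios of 0.5 or less for 56, 78, 42, 171 and 145 genes in the Nkx2.2, Nkx6.1, Olig2, Nkx6.1-P2A-Nkx2.2 and Nkx6.1-P2A-Olig2 lines. Of these 24, 29, 24, 111 and 89 were lower here by edgeR, and 161 genes of the table were lower in at least 1 line. The ratios carry no correction for library totals. After scaling by TMM, 47, 63, 30, 138 and 119 of those genes still had both ratios at 0.5 or less.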

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

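The comparisons between lines and of departures were planned, while the tests that weigh the 3 patterns below, and that of chromosome 18 between lines, were chosen after the main results were seen; those of the whole chromosome 18, of the control libraries and of thinned libraries were written before their own values were seen, and the others after. Among 103 values tested in the 5 control libraries, 2 had 1 library far from the other 4, where chance alone would set apart about 1 in 20. In both it was control replicate 5. Rlf was at 47.5 CPM there against 61.6 to 64.0 CPM (gap over range 0.872), and Zic2 was at 31.9 CPM against 54.7 to 61 CPM (0.831).

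Direct tests found differences between lines. Single-factor lines differed in 81 genes (Nkx2.2 against Nkx6.1), 257 genes (Nkx2.2 against Olig2) and 263 genes (Nkx6.1 against Olig2). With chromosomes 18 and Y left out of the fit these were 70, 63 and 43. The Nkx6.1-P2A-Nkx2.2 line differed from the Nkx6.1 and Nkx2.2 lines in 4 and 13 genes, and the Nkx6.1-P2A-Olig2 line from the Nkx6.1 and Olig2 lines in 11 and 81. Without those chromosomes the 81 became 27. Departures from the sum of single-factor effects were found for 1 gene, Rlf, in the Nkx6.1-P2A-Nkx2.2 line and for 3 Y-linked genes in the Nkx6.1-P2A-Olig2 line. For the latter line 0 passed by edgeR without chromosomes 18 and Y, and 188 without the term for the label series. The median log2 fold change of chromosome 18 between the Nkx6.1-P2A-Olig2 and Olig2 lines was -0.49, with 33 of its genes lower and 0 higher (camera p = 4.57e-37; p = 3.24e-06 with an estimated correlation).

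In the Olig2 line chromosome 18 had a median log2 fold change of 0.52. Activity of the Olig2 protein is argued against by the other line that makes it, where the median was -0.0246, and a scaling effect by the other autosomes, whose medians lay at most 0.0421 from 0. An extra copy of the whole chromosome is argued against by the first of 4 equal stretches, with a median of -0.0384. After those stretches were seen, windows of 5 Mb with at least 5 tested genes were examined: the 11 past 25 Mb had medians of 0.49 to 0.65, the 3 before 20 Mb -0.06 to 0.00, and the step lay between Celf4 (ending at 25754157, 0.14) and Pik3c3 (starting at 30272747, 0.58). An extra copy of the part of chromosome 18 beyond that step, at 1.47-fold the control, is a candidate explanation (lowest window 0.491), while toward the far end Socs6 (0.01) and Rttn (0.10), from 88665224 on, were near 0.

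Hprt, on the X chromosome (52988137 to 53021659), had log2 fold changes of -1.36, -0.86, -1.41, -1.67 and -1.42 in the Nkx2.2, Nkx6.1, Olig2, Nkx6.1-P2A-Nkx2.2 and Nkx6.1-P2A-Olig2 lines, and passed in all but the Nkx6.1 line (edgeR quasi-likelihood adjusted p = 0.106 there), though in the Olig2 line not in the fit without chromosomes 18 and Y (adjusted p = 0.0508). In this kind of line the inducible cassette lies beside Hprt, and Cre in the parental line is exchanged for the factor. The 7 tested genes within 0.5 Mb had medians of -0.71, -0.53, -0.23, -0.91 and -0.76 and the 10 at 0.5 to 2 Mb -0.50, -0.33, -0.39, -0.60 and -0.47, in the Olig2 line lower than the nearer genes. X genes over 10 Mb away had smaller medians, -0.00666, -0.087, -0.00996, -0.0749 and -0.0436. These argue against a change of the whole X as the full cause of the lower values near Hprt. A small fall of the whole X stays open in the Nkx6.1, Nkx6.1-P2A-Nkx2.2 and Nkx6.1-P2A-Olig2 lines. There X moved down at the preset correlation (camera adjusted p = 0.00026, 0.00187 and 0.035) but did not pass with an estimated correlation (lowest adjusted p = 0.0853). Of the 7 genes within 0.5 Mb, 0, 0, 0, 1 and 2 were lower in the 5 lines. Genes 2 to 10 Mb away had medians outside the range set for a local effect in the Nkx6.1 (-0.114) and Nkx6.1-P2A-Nkx2.2 (-0.184) lines. All tested X genes had medians of -0.0971 and -0.0861 in these lines. A local effect of the exchanged locus may account for the lower values near Hprt but stays open. The highest of the 5 nearby medians (-0.228) lay between the bounds set for it. Activity of the expressed factors cannot be told apart from a local effect, since 0 lines carry an inert sequence at the locus.

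More genes passed by edgeR in the 2-factor lines (399 and 397) than in the Nkx2.2 and Nkx6.1 lines (101 and 103), but at an unadjusted p under 0.05 the Nkx6.1 line had 2326 against 2028 and 2321. The label series is argued against as the whole cause, since with its term the smaller 2-factor count was 187 and the single-factor counts were 56 and 56. The control libraries of both series differed in 0 genes by edgeR, with 809 at an unadjusted p under 0.05. Depth is argued against too: with every library thinned to the smallest total the smaller 2-factor count was 350 and the larger of the Nkx2.2 and Nkx6.1 counts 97. DESeq2 called 486 genes in the Nkx6.1 line against 650 and 714, edgeR 283 in that line without control replicate 1, and direct tests between 2-factor and single-factor lines 4 to 81, so whether the 2-factor lines respond more than the Nkx6.1 line stays open, and differences between cell clones were not tested.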

How the results depend on the processing

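Limits first. Groups of 2 libraries give wide errors, and a line with 1 library left was assumed to vary like the other groups. Depth limits genes with few counts, for which only bounds or counting intervals are given. The labels do not say whether replicates were separate cultures. Counts of genes changed stayed within 1.5 times under median-of-ratios scaling, robust fitting, a filter at 5 CPM, limma with pseudocounts of 0.5 and 0.1 or quantile normalization, and libraries thinned to the smallest total, a setting chosen after seeing the data as were the fits without chromosomes 18 and Y and with the label number as a fixed edgeR block. Of the results for named genes, 2 lost their call with DESeq2, 5 with median-of-ratios scaling, 28 with thinned libraries, 72 with the other choice on the label series and 100 with only the compared groups in the fit. With 1 library left out, 1207 results for named genes kept their call and 620 lost it. For the changes below the cause was not tested, except where fewer libraries or genes were used.

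Values are given in the order Nkx2.2, Nkx6.1, Olig2, Nkx6.1-P2A-Nkx2.2 and Nkx6.1-P2A-Olig2 for lines against the control. The 4 comparisons of a 2-factor with a single-factor line are in the order Nkx6.1-P2A-Nkx2.2 against Nkx6.1 and Nkx2.2, then Nkx6.1-P2A-Olig2 against Nkx6.1 and Olig2. Departures from the sum are given for Nkx6.1-P2A-Nkx2.2 first. With limma on log2(CPM + 1), departures for Nkx6.1-P2A-Olig2 went from 3 to 1 genes. With no filter the comparisons of Nkx6.1-P2A-Nkx2.2 with Nkx6.1 and of Nkx6.1-P2A-Olig2 with Nkx6.1 and Olig2 had 11, 22 and 130 genes changed. With no abundance trend, Nkx6.1-P2A-Nkx2.2 against Nkx2.2 had 8. With the other choice on the label series (prefix set), the Nkx2.2, Nkx6.1, Nkx6.1-P2A-Nkx2.2 and Nkx6.1-P2A-Olig2 lines had 56, 56, 202 and 187 genes changed, of which 53, 53, 184 and 157 were shared, and the Nkx2.2 line had 33 changed 2-fold. The 4 comparisons then had 30, 30, 82 and 452, and the departures 3 and 188.

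DESeq2 gave 220, 486, 432, 650 and 714 genes changed, with 82, 92 and 225 changed 2-fold in the Nkx2.2, Nkx6.1 and Nkx6.1-P2A-Olig2 lines, 40, 51, 63 and 371 in the 4 comparisons, and departures of 9 and 68. It gave 287 for Nkx2.2 against Nkx6.1 and 550 for Nkx6.1 against Olig2. With only the compared groups in the fit, the Nkx2.2 line had 32 genes changed (18 changed 2-fold, 68.8% lower), Nkx6.1 62, Olig2 164 (35 changed 2-fold) and Nkx6.1-P2A-Olig2 261, the 4 comparisons 2, 3, 6 and 16, and Nkx2.2 against Olig2 7. Without chromosome 18 and Y genes, 59.8% of changed genes were lower in the Nkx2.2 line. The Olig2 line had 20 genes changed (16 changed 2-fold, 50% lower), Nkx6.1-P2A-Olig2 against Olig2 27, its departures 0 by edgeR (1751 genes had an unadjusted p under 0.05 in the test of all genes), Nkx2.2 against Olig2 63 and Nkx6.1 against Olig2 43. With an estimated correlation in camera, 1, 1, 0, 1 and 1 gene lists passed the threshold in place of 4, 18, 13, 12 and 12.

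With controls split by prefix set, and with the sets then exchanged, the overlap of lowered genes was 8 and 6 for Nkx2.2 and Nkx6.1, 3 and 4 for Nkx2.2 and Olig2, 27 and 21 for Nkx2.2 and Nkx6.1-P2A-Nkx2.2, 12 and 10 for Nkx2.2 and Nkx6.1-P2A-Olig2, 4 and 6 for Nkx6.1 and Olig2, 25 and 24 for Nkx6.1 and Nkx6.1-P2A-Nkx2.2, and 19 and 19 for Nkx6.1 and Nkx6.1-P2A-Olig2. It was 11 and 9 for Olig2 and Nkx6.1-P2A-Nkx2.2 (15 with all controls), 16 and 14 for Olig2 and Nkx6.1-P2A-Olig2, and 75 and 72 for the 2-factor lines. By direction only, 56, 78, 42, 170 and 144 genes of the deposited table were lower here.

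Libraries share only a number, and since the labels do not say what it marks and not every pair correlated over 0.1, the numbers were not taken as pairing. If the number that starts the label marks an experiment day, a block by it would account for that day, which the main model does not. Number 211 holds only Nkx6.1 replicate 2, so with a fixed block that library adds nothing to the comparisons of its line. Of 30 pairs of libraries with the same replicate number, 15 had a correlation of their deviations over 0.1 (-0.375 to 0.796), and 9 of 12 libraries matched their own number best, a hint from the data and not from the design. By the number that starts the label it was 7 of 10 pairs (-0.576 to 0.796). Deviations within a group of 2 mirror each other, so 2 such groups give the same correlation for both of their replicate numbers. Pairs that repeat a value in this way, such as 0.796 for the Nkx2.2 and Olig2 lines, are not separate evidence, and these counts include them. With the replicate block in edgeR, the Nkx6.1 line had 40 genes changed (24 changed 2-fold), Nkx2.2 against Nkx6.1 292 and Nkx6.1 against Olig2 607. The 4 comparisons then had 74, 59, 346 and 684, and the departures 2 and 21. Only controls carry replicate numbers 3, 4 and 5, so in this fit each line is compared with control replicates 1 and 2 alone. The term for the label series cannot be kept beside this block. These comparisons and departures therefore lack it, and should be set against the 30, 30, 82 and 452, and the 3 and 188, without that term. With a replicate block by label prefix in limma (consensus correlation 0.342), the lines had 154, 181, 396, 784 and 880 genes changed, the 4 comparisons 23, 36, 34 and 678, Nkx2.2 against Olig2 392, and departures 3 and 32. With a replicate block by label prefix in edgeR they had 269, 40, 2021, 1109 and 1269 (99, 15, 352, 369 and 357 changed 2-fold), Nkx2.2 against Nkx6.1 52, Nkx2.2 against Olig2 877, Nkx6.1 against Olig2 796, the 4 comparisons 11, 257, 19 and 2049, and departures 5 and 481. In that block fit Dll4 in Nkx6.1 against Olig2 went from -3.26 to 0.0262.

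With 1 library left out, genes changed in the lines ranged from 16 to 151, 1 to 283, 106 to 444, 89 to 531 and 81 to 550, and those changed 2-fold from 9 to 66, 1 to 98, 17 to 104, 61 to 211 and 45 to 204. The percent of changed genes that were lower ranged from 26.3 to 68.8, 0 to 82.5, 10.4 to 33.6, 63.0 to 70.0 and 64.4 to 71.6. The 4 comparisons ranged from 1 to 12, 1 to 21, 5 to 23 and 8 to 356, and departures from 1 to 1 and 2 to 10. Nkx2.2 against Nkx6.1 ranged from 4 to 42, Nkx2.2 against Olig2 from 123 to 163, and Nkx6.1 against Olig2 from 91 to 219.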

Other observations

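The list of imprinted genes used here was drawn up after the results were seen. Of 30 listed genes, which are expressed from 1 parental copy, 27 were tested, and 1, 0, 3, 3 and 2 were lower and 2, 0, 1, 1 and 2 higher in the Nkx2.2, Nkx6.1, Olig2, Nkx6.1-P2A-Nkx2.2 and Nkx6.1-P2A-Olig2 lines. Plagl1 was at 2.72 and 4.33 CPM in the Olig2 libraries and at 1.21 and 1.74 CPM in those of the Nkx6.1-P2A-Olig2 line. The 5 controls were at 22.2 to 83.8 CPM, with 22.2, 29.7 and 35.0 CPM in label series 21 and 83.8 and 60.4 CPM in series 23. It also fell in the Nkx6.1-P2A-Nkx2.2 line (-2.10 ± 0.46, SE). Mest, a maternally imprinted gene, fell by 3.59 ± 0.25 on the log2 scale in the Nkx6.1-P2A-Nkx2.2 line (edgeR quasi-likelihood adjusted p = 6.98e-06) and by 0.99 ± 0.21 in the Olig2 line. In the fit without chromosomes 18 and Y, Plagl1 alone of the 3 lower genes of the Olig2 line passed, with Mest at an edgeR quasi-likelihood adjusted p of 0.0954 and Ndn at 0.0907. Peg10 fell in the 2-factor lines (-1.50 ± 0.24 and -1.49 ± 0.24), and Dlk1 fell by 1.67 ± 0.29 in the Nkx2.2 line. Cdkn1c, a cell cycle inhibitor, rose in the Nkx2.2, Olig2, Nkx6.1-P2A-Nkx2.2 and Nkx6.1-P2A-Olig2 lines, by 0.77 ± 0.15, 0.87 ± 0.15, 1.09 ± 0.15 and 0.81 ± 0.15, and had a value of 0.02 in the Nkx6.1 line. Peg12 (1.22 ± 0.25, Nkx2.2 line) and Impact (0.53 ± 0.11, Nkx6.1-P2A-Olig2 line) rose and Ndn (-0.49 ± 0.10, Olig2 line) fell.

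Some genes were low in a single line. Rlf had 9.05 and 11.5 CPM in the Nkx2.2 libraries and 47.5 to 76.2 CPM in the other 13. Ttc27 fell by 1.07, B3galtl by 1.27 and Miip by 1.64 on the log2 scale in the Olig2 line, and were at 0.11, 0.15 and -0.26 in the Nkx6.1-P2A-Olig2 line, where none of them passed. These genes were chosen after their values were seen, and why they differed was not tested.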
